A study of Homo sapiens with 8 samples.

How the data were processed

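Expression was measured in 8 samples of the HepG2 cell line on single-channel whole-transcript oligonucleotide arrays, 4 from untreated cultures and 4 from cultures exposed to 0.5 mM H2O2 for 60 minutes. Per the labels' protocols, total RNA was purified on silica columns, its quality was read by spectrophotometry and a Bioanalyzer chip, and it was turned through cRNA into single-stranded sense cDNA that was labelled with biotin. The table analysed holds log2 expression values per probe set and array, as deposited by the authors. The lowest value of each array is 2.02 or less and the highest 13.73 or more, and the arrays' medians, given with the results, lie close together. How the probes were summarized into probe sets and how the arrays were normalized is not given in the sources used here, so the scale is known from the values to be logarithmic and the normalization stays unknown. The submitters' processing notes name limma, with no role and no version. No array's scanner output, background estimate or detection call was used here. For arrays, their number limits the precision.

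The table has 32321 probe sets. The platform annotation pairs 19158 of them with 1 gene symbol, 1388 with several symbols and 11775 with none, which are unnamed here. Entrez identifiers of 19128 of the 19158 were found in a RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. It served only for names and to limit which genes could be named among the largest changes. No genome build is named for the values, so no coordinates are given. Tests used the probe sets with 1 symbol, which gave 18404 genes. For the 637 genes with several probe sets, the one with the highest mean log2 over all arrays was taken, and 5 of these genes had probe sets called in opposite directions. No pair of arrays shared more than 0.00619% identical values, so each array counted as 1 sample. All per-sample columns were used.

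The groups are those of the sample labels. One comparison was made, H2O2 minus untreated, with limma (version 3.58.1 in R 4.3.3): a linear model with 1 mean per group, empirical Bayes moderation of the variances and Benjamini-Hochberg adjustment over all genes, with a call at an adjusted p under 0.05. Every adjusted p of a gene comes from this model unless another is named. Counts adjusted over the list alone apply the same adjustment to the p-values of that list's measured members. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over 42 lists, and again with an estimated correlation and with fry. camera asks whether a list's members rank differently from all other genes, and fry whether they move, on balance, one way. Splits of the samples, artifact checks, symbol families and figures used the same R and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

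The test, the groups, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule names the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap and that the RefSeq gene table holds. It adds 20 genes chosen for senescence and liver function whatever their value, of which 18 had a value. For each list it adds up to 2 of the largest called rises and up to 2 of the largest called falls. Genes named outside the rule are said to be chosen after their values were seen. The lists cover p53 target genes, cyclin-dependent kinase inhibitors and RB family, DNA replication and S phase, mitosis and G2/M, replication-dependent histones, nuclear lamina and high mobility group proteins, homologous recombination and Fanconi anaemia repair, senescence-associated cytokines and chemokines, senescence-associated proteases, inhibitors and growth factors, NF-kB inhibitors and targets, interferon response, NRF2 target genes, other antioxidant enzymes, metallothioneins, heat shock proteins and chaperones, unfolded protein response and ATF4 targets, apoptosis regulators, lysosome and autophagy, immediate early genes and iron handling. For liver functions they cover plasma proteins made by hepatocytes, complement and acute phase proteins, cytochrome P450 and phase II detoxification, liver transcription factors, urea cycle and amino acid breakdown, cholesterol synthesis and SREBP2 targets, fatty acid and triglyceride synthesis, fatty acid oxidation and ketogenesis, bile acid synthesis and transport, glycolysis and hypoxia targets, gluconeogenesis and glycogen, nuclear-encoded oxidative phosphorylation, cytosolic ribosomal proteins, and ribosome biogenesis and MYC targets. For cell state and other cell types they cover mesenchymal and actin cytoskeleton genes, YAP target genes, epithelial junction genes, biliary and progenitor markers, fetal liver and tumour markers, stellate cell and fibroblast markers, macrophage and leukocyte markers, and endothelial markers.

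The alternatives tried were the replicate number as a block, quantile normalization, median centring, leaving out dim genes, those above the array median on fewer than 4 arrays, the mean of a gene's probe sets, every probe set on its own, a variance trend with robust moderation, array weights, an unmoderated test, limma's treat against a fold of 1.5, an estimated correlation or fry for the lists, and leaving out each array in turn. The steps were first tested on simulated data. With 200 of the 18404 genes changed in data simulated for this comparison, the limma step recovered 76.5% of 68 genes changed by 0.5 log2, 100% of 66 changed by 1 and 100% of 66 changed by 2, with 8 false calls (4.17% of all calls). Genes were simulated independently of each other, here and for camera. These runs therefore do not show how either step behaves with correlated genes or with a larger share of changed genes. camera called upward 5 of 5 lists shifted up by 0.5 and 0 of 30 lists that were not shifted and shared no members with those. Downward calls among these 30 lists were not counted. The test of symbol families, run on the 18404 genes in shuffled order, found a planted family of 23 with 15 members called in 10 of 10 shuffles and with 12 members called in 0 of 10, and called 0 other families. Shuffling removes any correlation within families, so this does not show how the test behaves for genes that vary together.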

Results

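HepG2, a human liver tumour cell line that keeps many hepatocyte functions, was profiled on 8 single-channel expression arrays. Cells in 4 cultures had been exposed for 60 minutes to 0.5 mM hydrogen peroxide (H2O2), an oxidant used here to bring on senescence, a lasting arrest of cell division. The other 4 cultures received medium alone. Per the labels, 5 days passed between the exposure and the tests for a senescent phenotype; no separate time is given for taking RNA. The design text calls the 4 cultures of each condition biological replicates, and their number limits the precision of every value below. Median log2 values were 6.89, 6.88, 6.85 and 6.93 in untreated replicates 1 to 4, and 6.87, 6.87, 6.92 and 6.89 in H2O2 replicates 1 to 4. Across all probe sets, which are not independent replicates, Pearson's r lay between 0.990 and 0.996 for arrays of one group. It lay between 0.979 and 0.985 for arrays of different groups. The first principal component held 74.6% of the variance and separated the groups, and the next held 9.22%.

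The comparison asked which transcripts differ between cells treated with H2O2 to make them senescent and untreated cells. Genes of the p53 response rose together, led by CDKN1A, the cyclin-dependent kinase inhibitor p21, which was 5.13-fold higher (log2 difference 2.36 ± 0.067). The lists for DNA replication, mitosis, replication-dependent histones, cholesterol synthesis, glycolysis and hypoxia, gluconeogenesis and plasma proteins passed camera, a test of gene lists, downward at its preset correlation. These 7 calls were lost with an estimated correlation, at adjusted p = 0.0644 to adjusted p = 0.430. Mesenchymal and actin cytoskeleton genes rose as a list under both, and the lysosome and autophagy list passed upward at the preset correlation but at adjusted p = 0.252 with an estimated correlation. All log2 differences are H2O2 minus untreated with their standard error, levels are means with their SD, and n = 4 arrays per group throughout.

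The largest rise was that of LYVE1, a hyaluronan receptor best known from lymphatic endothelium, from 5.63 ± 0.23 to 10.70 ± 0.081, or 33.4-fold (limma, Benjamini-Hochberg adjusted p = 3.18e-12). CPA4, a carboxypeptidase, rose by 4.02 ± 0.10, and CD109, a membrane protein that binds transforming growth factor beta, by 3.60 ± 0.14. MMP3, the matrix protease stromelysin-1, rose by 3.49 ± 0.086, and IL18, an inflammatory cytokine, by 3.37 ± 0.12. The vesicle trafficking GTPases RAB31 (3.49 ± 0.083) and RAB3B (3.45 ± 0.17), the long non-coding RNA UCA1 (3.45 ± 0.13), MYOF, a membrane repair protein (3.43 ± 0.10), the annexin ANXA3 (3.34 ± 0.088), the tetraspanin TSPAN1 (3.32 ± 0.091) and the lipase LIPH (3.30 ± 0.10) completed the 12 largest rises. In untreated cells 11 of these 12 genes lay below the array median of 6.89, a level not shown to lie above background, which limits how exactly their fold is known.

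Among the falls, LOX, the enzyme that cross-links collagen and elastin, changed most, from 10.78 ± 0.16 to 7.53 ± 0.23 (log2 difference -3.24 ± 0.11, limma adjusted p = 1.43e-10). G6PC1, which releases free glucose from glucose 6-phosphate, fell by 3.02 ± 0.16 on the log2 scale. HAL, the first enzyme of histidine breakdown, fell by 2.57 ± 0.10, and ARG1, the arginase that ends the urea cycle, by 2.20 ± 0.090. PFKFB4, a regulator of glycolysis, fell by 2.01 ± 0.068, and LEAP2, a secreted liver peptide, by 2.07 ± 0.15. DEPP1 (-2.15 ± 0.097), the tubulin TUBB1 (-1.97 ± 0.088) and TNS1, a focal adhesion protein (-1.96 ± 0.15), were also among the 12 largest falls. The other 3 were the histones H2BC3 (-2.36 ± 0.28), H2AC4 (-2.02 ± 0.18) and H1-5 (-2.02 ± 0.21), whose values are uncertain because histone genes have near-identical copies. In treated cells 3 of these 12 genes, ARG1 (4.50 ± 0.12), HAL (5.87 ± 0.039) and H2AC4 (6.83 ± 0.43), lay below the array median, which limits their fold in the same way.

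**Figure D1:**
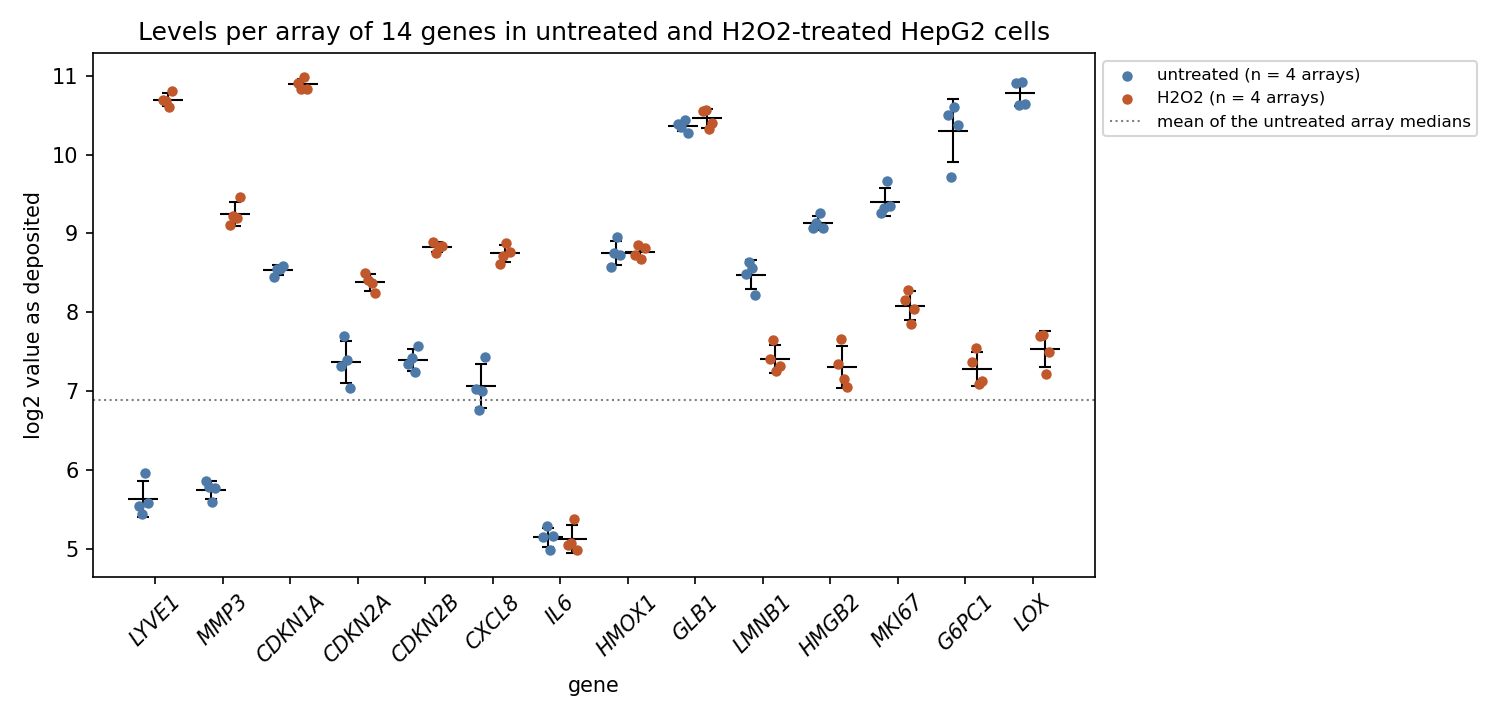
Log2 values as deposited of 14 genes in each of the 4 untreated and 4 H2O2-treated arrays, with the group mean and SD. LYVE1 lies at 5.63 in untreated and 10.70 in treated cells on average, and LOX at 10.78 and 7.53.

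Of the genes chosen beforehand as markers of senescence, several beside CDKN1A passed the test. CDKN2B, which encodes the kinase inhibitor p15, rose by 1.43 ± 0.078 and CDKN2A, which encodes p16 and p14ARF, by 1.02 ± 0.11, from 7.36 ± 0.27 to 8.38 ± 0.11. MDM2, the p53 ubiquitin ligase, rose by 0.77 ± 0.065, and GDF15, a secreted stress cytokine, by 0.68 ± 0.068. LMNB1, the nuclear lamin whose loss accompanies senescence, fell by 1.07 ± 0.10, the chromatin protein HMGB2 by 1.83 ± 0.11, the proliferation marker MKI67 by 1.32 ± 0.10 and the mitotic cyclin CCNB1 by 0.75 ± 0.13. The chemokine CXCL8 rose by 1.69 ± 0.12, whereas IL6 (-0.023 ± 0.093, adjusted p = 0.886) and CCL2 (-0.016 ± 0.091, adjusted p = 0.917) did not pass, at 5.15 ± 0.12 and 6.02 ± 0.15 in untreated cells, below the array median. GLB1, the lysosomal beta-galactosidase behind the common senescence stain, differed by 0.096 ± 0.074 (adjusted p = 0.361). The oxidant response genes HMOX1 (0.016 ± 0.083) and NQO1 (0.0050 ± 0.070) did not pass either. IGFBP3 gave -0.32 ± 0.14 (adjusted p = 0.0969), and its call depended on the fit and on untreated replicate 2, without which it passed at -0.49. The hepatocyte product ALB fell by 0.24 ± 0.066 and the fetal liver protein AFP by 0.56 ± 0.077. Of the 20 genes so chosen, 18 had a value.

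Among 32 measured p53 target genes 29 rose and 0 fell, with the same counts adjusted over the list alone (median log2 difference 0.83, camera adjusted p = 2.62e-20). TIGAR, which lowers glycolytic flux, rose by 2.19 ± 0.12. The cyclin-dependent kinase inhibitors and RB family went both ways, with 3 of 10 higher and 4 lower (3 and 4 adjusted over the list alone, camera adjusted p = 0.919). CDKN1A and CDKN2B rose while the kinase inhibitor CDKN1B (-0.81 ± 0.076) and the RB relative RBL1 (-0.66 ± 0.098) fell, so the list's median (-0.14) and its camera test lay below 0 and its mean (0.23) above. In the list for mitosis and G2/M 58 of 59 genes fell and 0 rose (58 and 0 adjusted over the list alone, median -1.10, camera adjusted p = 9.31e-33), but adjusted p = 0.252 with an estimated correlation. The mitotic kinesin KIF15 was 3.48-fold lower (8.77 ± 0.061 against 6.97 ± 0.43), and the kinetochore protein NUF2 fell by 1.67 ± 0.17. DNA replication and S phase genes fell in 38 of 44 cases and rose in 0 (39 and 0 adjusted over the list alone, median -0.70, camera adjusted p = 1.54e-17, adjusted p = 0.306 with an estimated correlation). The primase subunit PRIM1 fell by 1.11 ± 0.083 and the replicative helicase subunit MCM2 by 1.07 ± 0.092.

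Homologous recombination and Fanconi anaemia repair genes were lower in 22 of 24 cases and higher in 0, as when adjusted over the list alone (median -0.76, camera adjusted p = 4.54e-13, adjusted p = 0.252 with an estimated correlation). MND1, 2.82-fold lower (8.08 ± 0.16 against 6.59 ± 0.34), and RAD51AP1 (-1.32 ± 0.17), which both promote strand exchange, fell most. Of 39 replication-dependent histones 30 fell and 1 rose (31 and 1 adjusted over the list alone, median -0.80, camera adjusted p = 4.54e-13, adjusted p = 0.332 with an estimated correlation). The exception was H4C8, at 1.77 ± 0.082, and all of these values are uncertain for near-identical copies. For nuclear lamina and high mobility group proteins, 11 of 17 fell and 2 rose, as when adjusted over the list alone (median -0.24, camera adjusted p = 0.00108, adjusted p = 0.377 with an estimated correlation). LMNB1 and HMGB2 fell while LMNA, which encodes lamins A and C, rose by 0.63 ± 0.081.

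**Figure D2:**
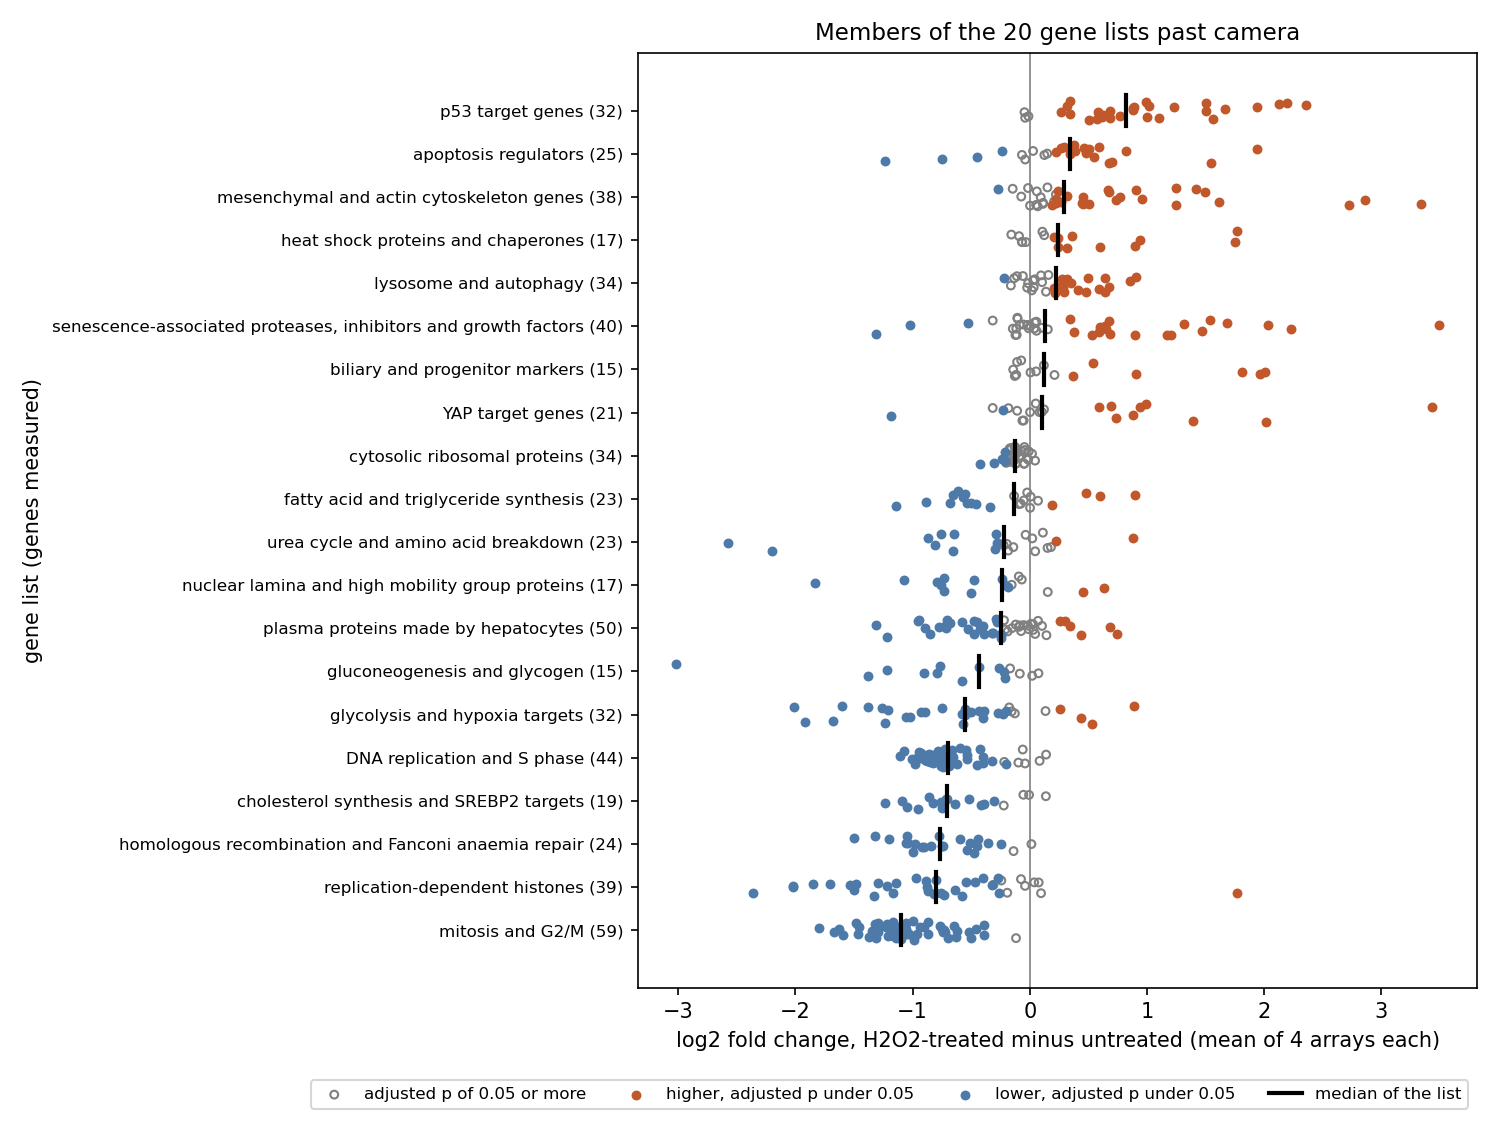
Log2 difference, H2O2-treated minus untreated (means of 4 arrays each), of each measured member of the 20 gene lists past camera, coloured by its limma call, with the median of the list as a bar. Medians run from -1.10 for mitosis and G2/M to 0.83 for the p53 target genes, and H4C8 at 1.77 is the histone that rose.

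Senescence-associated proteases, inhibitors and growth factors rose in 19 of 40 cases and fell in 3, as when adjusted over the list alone (median 0.13, camera adjusted p = 7.21e-05, adjusted p = 0.141 with an estimated correlation). MMP3 and IGFBP7 (2.23 ± 0.066), an insulin-like growth factor binding protein, rose, while IGFBP1 (-1.31 ± 0.074) and the angiogenic factor VEGFA (-1.03 ± 0.067) fell. In the list of senescence-associated cytokines and chemokines 7 of 29 rose and 3 fell, as when adjusted over the list alone (camera adjusted p = 0.479). CXCL8 and LIF (1.37 ± 0.089) rose and CCL20 fell by 1.87 ± 0.097, and the list's median (-0.016) lay below 0, though above it after quantile normalization, while its mean (0.11) and test lay above. NF-kB inhibitors and targets were mostly not called, with 4 of 16 higher and 1 lower, as when adjusted over the list alone (camera adjusted p = 0.772, median -0.024 below 0, mean 0.0028 and test above). The transcription factor IRF1 rose by 0.39 ± 0.069 and SOD2, a mitochondrial superoxide dismutase, fell by 0.76 ± 0.094. Of 32 interferon response genes 12 rose and 4 fell, as when adjusted over the list alone (camera adjusted p = 0.0943). OAS1, an antiviral synthetase, rose by 1.36 ± 0.074 and the RNA sensor RIGI by 0.88 ± 0.092, and USP18 fell by 0.41 ± 0.089.

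NRF2 target genes were higher in 6 of 25 cases and lower in 6, as when adjusted over the list alone (camera adjusted p = 0.808), with the transporter ABCC3 at 1.40 ± 0.071 and TKT, of the pentose phosphate pathway, at -0.44 ± 0.066. Other antioxidant enzymes rose in 7 and fell in 9 of 31 cases (8 and 10 adjusted over the list alone, camera adjusted p = 0.772, median -0.056 and test below 0, mean 0.0059 above). The glutathione peroxidases GPX8 (0.93 ± 0.099) and GPX1 (0.92 ± 0.071) rose and GPX3 fell by 0.56 ± 0.082. Among metallothioneins, metal-binding proteins with near-identical copies and thus uncertain values, 4 of 9 rose and 0 fell, as when adjusted over the list alone (camera adjusted p = 0.0746, under 0.05 with the replicate number as a block). MT2A rose by 0.44 ± 0.062. Heat shock proteins and chaperones rose in 10 of 17 cases and fell in 0 (10 and 1 adjusted over the list alone, median 0.24, camera adjusted p = 0.00129, adjusted p = 0.377 with an estimated correlation). The small heat shock proteins HSPB8 (1.77 ± 0.13) and CRYAB (1.75 ± 0.073) led.

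Unfolded protein response and ATF4 targets fell in 11 and rose in 7 of 31 cases (13 and 7 adjusted over the list alone, median -0.11, camera adjusted p = 0.0623). That list passed camera when dim genes were left out, which kept 30 of its 31 members, and without untreated replicate 4, H2O2 replicate 1 or H2O2 replicate 2. PHGDH, the first enzyme of serine synthesis, fell by 0.999 ± 0.067 and the stress gene DDIT4 by 1.11 ± 0.12, and the phosphatase subunit PPP1R15A rose by 0.99 ± 0.068. Apoptosis regulators rose in 16 of 25 cases and fell in 4, as when adjusted over the list alone (median 0.34, camera adjusted p = 0.00108, adjusted p = 0.141 with an estimated correlation). The death receptor FAS, which the p53 list also holds, rose by 1.94 ± 0.099 and PMAIP1, a killer protein of the BCL2 family, by 1.55 ± 0.097. BNIP3, a hypoxia-regulated mitophagy receptor, fell by 1.24 ± 0.065. Lysosome and autophagy genes rose in 19 of 34 cases and fell in 1, as when adjusted over the list alone (median 0.22, camera adjusted p = 0.000149, adjusted p = 0.252 with an estimated correlation). The proton pump subunit ATP6V0D1 rose by 0.90 ± 0.086 and SQSTM1, the autophagy receptor p62, by 0.85 ± 0.062. The gene that fell was GUSB, a glucuronidase (-0.22 ± 0.079), a call that was lost in most other settings, leaving out most single arrays included. Immediate early genes, the first to respond to growth signals, rose in 9 and fell in 6 of 24 cases (10 and 7 adjusted over the list alone, camera adjusted p = 0.198), with JUN at 1.40 ± 0.090 and the kinase SGK1 at -0.92 ± 0.074. Of 16 iron handling genes 7 fell and 2 rose, as when adjusted over the list alone (camera adjusted p = 0.190). The ferroxidase CP fell by 1.60 ± 0.14 and the iron exporter SLC40A1 rose by 1.32 ± 0.063.

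Many products of hepatocytes were lower in treated cells. Plasma proteins made by hepatocytes fell in 26 of 50 cases and rose in 6 (28 and 6 adjusted over the list alone, median -0.24, camera adjusted p = 3.19e-05, adjusted p = 0.430 with an estimated correlation). APOC3, an apolipoprotein of triglyceride-rich particles, fell by 1.31 ± 0.094 and PLG, plasminogen, by 1.22 ± 0.093, while HPX, a heme carrier, rose by 0.74 ± 0.13. Complement and acute phase proteins went both ways, with 9 of 23 lower and 4 higher, as when adjusted over the list alone (camera adjusted p = 0.295), such as the complement protease C1S at 1.23 ± 0.11 and the pore component C8A at -0.73 ± 0.15. Of 36 genes for cytochrome P450 and phase II detoxification 11 rose and 7 fell (11 and 9 adjusted over the list alone, camera adjusted p = 0.772, median -0.085 below 0, mean 0.086 and test above). AOX1 (1.57 ± 0.10) and CYP3A5 (1.46 ± 0.10), which oxidise drugs, rose, and the alcohol dehydrogenase ADH6 fell by 1.08 ± 0.10. Liver transcription factors fell in 6 and rose in 3 of 18 cases (7 and 3 adjusted over the list alone, camera adjusted p = 0.138), with HNF4G at -1.23 ± 0.10 and FOXA2 at -0.54 ± 0.067. Urea cycle and amino acid breakdown genes fell in 11 of 23 cases and rose in 2 (12 and 3 adjusted over the list alone, median -0.22, camera adjusted p = 0.00207, adjusted p = 0.386 with an estimated correlation). HAL and ARG1 fell most and HPD, a dioxygenase of tyrosine breakdown, rose by 0.88 ± 0.064.

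Cholesterol synthesis and SREBP2 targets were lower in 15 of 19 cases and higher in 0, as when adjusted over the list alone (median -0.71, camera adjusted p = 3.01e-07, adjusted p = 0.377 with an estimated correlation). ACAT2 (-1.24 ± 0.14) and HMGCS1 (-1.09 ± 0.15), which act early in the pathway, fell most. Fatty acid and triglyceride synthesis genes fell in 11 of 23 cases and rose in 4, as when adjusted over the list alone (median -0.13, camera adjusted p = 0.0160, adjusted p = 0.430 with an estimated correlation). The lipase PNPLA3 fell by 1.14 ± 0.11 and the elongase ELOVL6 by 0.89 ± 0.11, while the elongase ELOVL1 rose by 0.90 ± 0.066. Among 23 genes of fatty acid oxidation and ketogenesis 7 fell and 2 rose (8 and 2 adjusted over the list alone, camera adjusted p = 0.0866), with HADH, of the beta-oxidation spiral, at -1.11 ± 0.11. That list passed without untreated replicate 4 and without H2O2 replicate 2. Bile acid synthesis and transport genes fell in 6 and rose in 2 of 19 cases, as when adjusted over the list alone (camera adjusted p = 0.138), with CYP8B1, a sterol hydroxylase, at -0.61 ± 0.12.

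Glycolysis and hypoxia targets fell in 24 of 32 cases and rose in 4 (25 and 4 adjusted over the list alone, median -0.55, camera adjusted p = 2.31e-11, adjusted p = 0.146 with an estimated correlation). PFKFB4 fell, as did PDK1, which restrains pyruvate entry into mitochondria (-1.92 ± 0.077), while the phosphofructokinase PFKP (0.89 ± 0.084) and the hexokinase HK1 (0.53 ± 0.088) rose. Gluconeogenesis and glycogen genes fell in 11 of 15 cases and rose in 0, as when adjusted over the list alone (median -0.43, camera adjusted p = 6.01e-06, adjusted p = 0.0644 with an estimated correlation). After G6PC1, the coactivator PPARGC1A fell most (-1.38 ± 0.094). Nuclear-encoded oxidative phosphorylation genes mostly did not pass, with 5 of 36 higher and 2 lower, as when adjusted over the list alone (camera adjusted p = 0.746), such as the complex I subunit NDUFB3 at 0.67 ± 0.10 and the complex III subunit CYC1 at -0.45 ± 0.067. Cytosolic ribosomal proteins fell in 5 of 34 cases and rose in 0, as when adjusted over the list alone (median -0.13, camera adjusted p = 0.00316, adjusted p = 0.430 with an estimated correlation), among them RPL13 at -0.30 ± 0.066. Ribosome biogenesis and MYC targets fell in 6 and rose in 3 of 27 cases, as when adjusted over the list alone (camera adjusted p = 0.159), with the nucleolar methyltransferase FBL at -0.57 ± 0.065 and MYC itself at -0.53 ± 0.065.

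**Figure D3:**
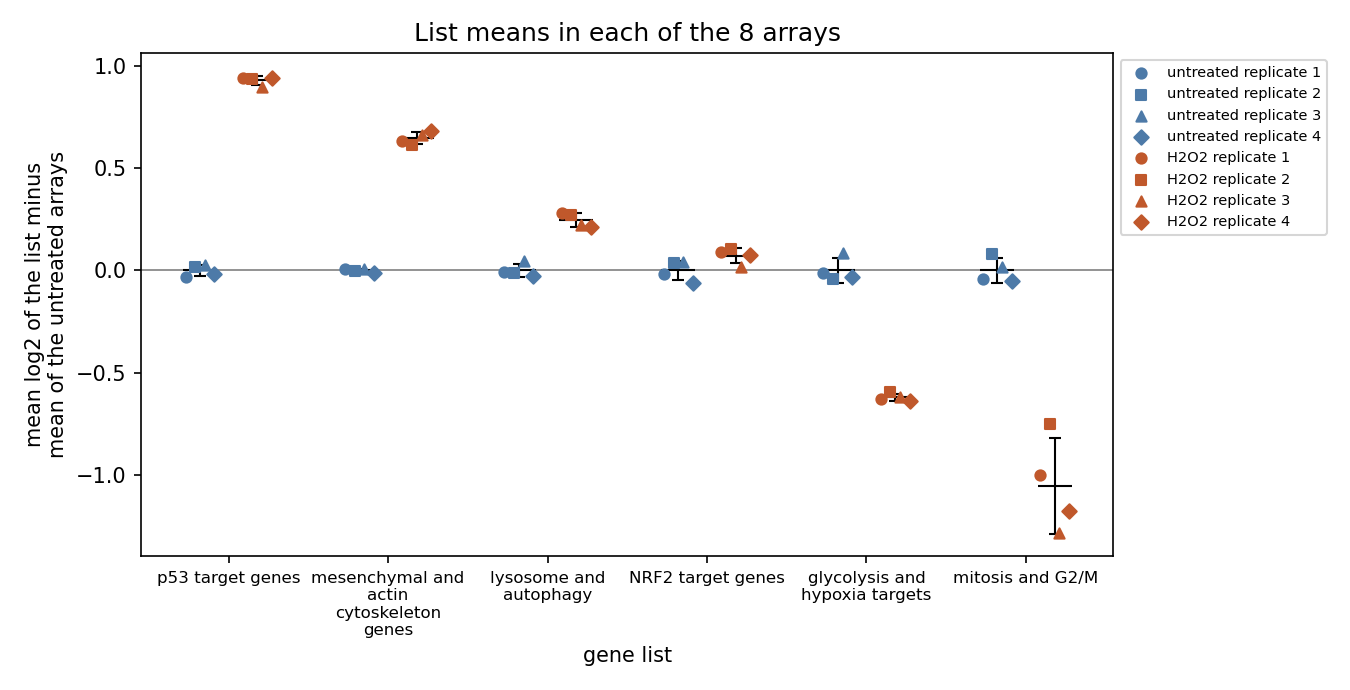
Mean log2 value of 6 gene lists in each of the 8 arrays, set to 0 at the mean of the untreated arrays, with group mean and SD. The treated arrays average 0.93 for the p53 target genes, 0.072 for the NRF2 target genes and -1.05 for mitosis and G2/M.

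Mesenchymal and actin cytoskeleton genes rose in 24 of 38 cases and fell in 1 (27 and 1 adjusted over the list alone, median 0.29, camera adjusted p = 9.43e-11). Beside ANXA3, the calcium-binding protein S100A11 rose by 2.86 ± 0.098, and ZEB1, a repressor of epithelial genes, fell by 0.27 ± 0.066. YAP target genes, which respond to cell tension and density, rose in 9 and fell in 2 of 21 cases (9 and 3 adjusted over the list alone, median 0.10, camera adjusted p = 0.00827, adjusted p = 0.351 with an estimated correlation). MYOF and ANKRD1 (2.02 ± 0.10) rose while the matricellular protein CCN2 fell by 1.18 ± 0.068. Epithelial junction genes rose in 5 and fell in 1 of 17 cases, as when adjusted over the list alone (camera adjusted p = 0.163). The tight junction claudin CLDN6 rose 4.01-fold (7.01 ± 0.098 to 9.02 ± 0.15), the adherens junction cadherin CDH1 rose by 0.81 ± 0.16, and CLDN14 fell by 0.65 ± 0.089. Biliary and progenitor markers rose in 6 of 15 cases and fell in 0, as when adjusted over the list alone (median 0.12, camera adjusted p = 0.0121, adjusted p = 0.150 with an estimated correlation), led by CD24 (2.01 ± 0.19) and the keratin KRT23 (1.96 ± 0.068). Of 15 fetal liver and tumour markers 5 fell and 2 rose (6 and 2 adjusted over the list alone, camera adjusted p = 0.144), with the Notch ligand DLK1 at -0.52 ± 0.064 and the trypsin inhibitor SPINK1 at 0.81 ± 0.12.

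Some genes best known as markers of other cell types moved with the treatment. Stellate cell and fibroblast markers rose in 3 and fell in 1 of 16 cases, as when adjusted over the list alone (camera adjusted p = 0.641). The smooth muscle actin ACTA2, which the mesenchymal list also holds, rose 2.83-fold (10.05 ± 0.096 to 11.55 ± 0.076) and the growth factor receptor PDGFRB fell by 1.15 ± 0.088. The median of that list (-0.0099) lay below 0 and its mean (0.076) and test above, and the median turned positive after quantile normalization. Macrophage and leukocyte markers rose in 6 and fell in 0 of 18 cases, as when adjusted over the list alone (camera adjusted p = 0.0866), such as LAPTM5, a lysosomal protein of blood cells, at 2.27 ± 0.074 and the T cell receptor subunit CD3D at 1.48 ± 0.085. Here too the median (-0.0023) lay below 0, turning positive after quantile normalization, and the mean (0.32) and test above. Endothelial markers rose in 3 and fell in 1 of 15 cases, as when adjusted over the list alone (median 0.075, camera adjusted p = 0.158), with the receptor TIE1 at 1.67 ± 0.077 beside LYVE1. The cadherin CDH5 fell by 0.25 ± 0.073, a call lost without untreated replicate 4 or without H2O2 replicate 1. The leukocyte list passed camera without untreated replicate 1. Both it and the endothelial list also passed when dim genes were left out, but this adds no support for a rise of either list. Of the 8 leukocyte and 6 endothelial markers kept, 3 in each list, LAPTM5, CD3D and CD79A, and LYVE1, TIE1 and ESAM (CD79A and ESAM named after their values were seen), lay below the array median in untreated cells and were kept because they rose, while unchanged dim markers were dropped. In untreated cells 5 of the 16 stellate, 5 of the 18 leukocyte and 4 of the 15 endothelial markers lay above the array median.

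In limma's test of 18404 genes, 3527 were higher and 2732 lower in treated cells at a Benjamini-Hochberg adjusted p under 0.05, or 34.0% of all. At least 2-fold changes numbered 346 up and 206 down. The groups did not overlap in 33.7% of all genes tested, against 2.86% by chance in a 4 against 4 comparison, whose smallest exact two-sided p is 0.0286. Of 42 gene lists 20 passed camera with its preset correlation, 8 upward and 12 downward. Of these, 2 also passed with an estimated correlation, the p53 target genes and the mesenchymal and actin cytoskeleton genes (camera adjusted p = 0.0260 for each). Some lists share members, such as FAS in the p53 and apoptosis lists, so the 20 are not all separate results. No detection calls came with the values, so a level below the array median is not shown to be above background, and which scaling or normalization the values carry stays unknown.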

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

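The tests of the glycolysis, cell marker and mitosis patterns below were chosen only after the results were seen, while the comparison with other splits of the samples was planned.

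Of 168 groups of 4 arrays, 5 held an array whose gap to its nearest neighbour exceeded Dixon's limit, where chance gives about 1 in 20, or 8.4. MYOF in H2O2 replicate 4 lay 0.39 above the mean of the other treated arrays, at 9.35 against 8.93 to 8.98. IGFBP3 in untreated replicate 2 lay at -0.69 from the others' mean, at 7.36 against 7.99 to 8.11. The mean of the p53 target genes in H2O2 replicate 3 differed by -0.043 from that of the other treated arrays, and the mean of the unfolded protein response and ATF4 targets in untreated replicate 4 by -0.068 from that of the other untreated arrays. Stellate cell and fibroblast markers averaged 0.19 higher in H2O2 replicate 3 than in the other treated arrays. Outside the genes tested, 29 of the 11775 probe sets with no symbol were at least 2-fold higher and 29 at least 2-fold lower in treated cells at a limma adjusted p under 0.05. Among the 1388 probe sets with several symbols 23 were at least 2-fold higher and 15 at least 2-fold lower.

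Glycolysis and hypoxia targets had a median log2 difference of -0.55, with 24 of 32 genes lower and 4 higher. As a list they passed camera at its preset correlation but not with an estimated one (adjusted p = 0.146), so a fall of the whole list beyond that of other genes is not settled, and the tests below concern the median. The unknown normalization of bright genes is argued against as the whole cause, since the lowest median among 10000 random lists matched on mean expression was -0.21. A fall of the glycolytic pathway alone is argued against too, since hypoxia targets outside glycolysis had a median of -0.93, with 10 of 13 lower, against -0.43 in the glycolytic part. Fewer cells and therefore more oxygen in the treated wells and an effect of the treatment on each cell cannot be told apart, since YAP target genes, which also respond to density, had a median of 0.10 over members that moved both ways, and cell numbers were not analysed here.

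Single markers of endothelium (LYVE1, TIE1) and of leukocytes (LAPTM5, CD3D) rose in treated cells. Cells of these types would bring their abundant transcripts together. The median over all measured endothelial markers was 0.075 (interquartile range 0.22), and over all leukocyte markers -0.0023 (interquartile range 0.64). The smallest rises of their 3 top genes, 1.59 and 1.12, lay above these medians. The top 3 genes of any such list lie above its median, so that comparison decides nothing. The medians near 0 show that most markers did not rise with the top genes. For the endothelial list this argues against endothelial cells in the treated wells as the main source. The leukocyte list pools markers of macrophages, T cells, B cells and other types, so its median cannot decide on a single type. Most markers of both lists lay below the array median in untreated cells, and a small share of endothelial cells or leukocytes is not excluded. What raised these genes in the treated wells stays open, the treatment included, and was not tested.

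The mean of the mitosis genes ranged over 0.53 between treated arrays and over 0.13 between untreated arrays. Whether these ranges differ beyond chance was not tested, and the list was picked among 42 after the results were seen. A shift of whole arrays is argued against, since the treated arrays' medians lay between 6.87 and 6.92. After median centring the ranges were 0.58 and 0.18, but with medians so close centring could change them little. Other differences in scaling, such as in the spread of an array's values, were not tested and stay open. A single array and a spread over all treated wells cannot be told apart, since the range was 0.42 without H2O2 replicate 3, which had the lowest array weight among them (0.369), but 0.285 without H2O2 replicate 2, the treated array with the highest mean. If treated wells held differing shares of untreated-like cells, the range of the mitosis genes would need a range of 0.20 in the mean of the p53 target genes, but that mean ranged over 0.046 between treated wells and over 0.060 between untreated wells, which argues against such a mix as the whole cause. Chance and differences in culture or in the degree of arrest between wells stay open and untested.

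Across the 35 splits of the 8 arrays into 4 and 4, only the real split reached the gene counts, which argues against chance. This is the smallest share that 35 splits can give. The other splits mix treated and untreated arrays, so a treatment difference adds to their spread. Their counts therefore do not measure chance alone. The real split gave 3527 higher and 2732 lower genes, 346 and 206 of them at least 2-fold, and the highest of the other splits gave 0 in each case, so 1 of the 35 splits reached each count. For the number of gene lists passing camera chance cannot be excluded, with 20 lists in the real split, 25 in the highest of the other splits and 7 of the 35 splits with as many. Camera ranks all genes within a split, so a list can pass it in a split that calls 0 genes. Splits with unequal numbers of treated arrays on their sides still carry part of the treatment difference. Lists passing there need not do so by chance, so the splits cannot decide the question.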

How the results depend on the processing

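None of these alternatives was chosen after the results were seen. The counts of higher and lower genes were 3527 and 2732, and 3288 and 2470 with the replicate block, 3630 and 2813 after quantile normalization, 3394 and 2674 after median centring, 3508 and 2732 with the mean of a gene's probe sets, 3752 and 3253 among probe sets each tested on its own, 3669 and 2809 with a variance trend and robust moderation, and 3236 and 2373 in the unmoderated test. Array weights called 4262 higher and 4111 lower genes, and the cause of the larger count of lower genes was not tested. Calls were 56.4% higher ones in the model as designed, 50.9% with array weights, 53.6% among probe sets each tested on its own and between 54.6% and 58.8% in the other settings compared. Leaving out single arrays gave 3110 to 3686 higher and 2228 to 3069 lower genes, 333 to 362 and 174 to 255 of them at least 2-fold, and 20 to 22 lists past camera. At least 2-fold changes otherwise numbered 298 to 410 up and 183 to 254 down, and 476 up and 253 down passed limma's treat against a fold of 1.5. Of the 6259 called genes 0 were called the other way in any setting with 1 value per gene, and 5628 were called the same way with the replicate block. Same-numbered arrays of the groups did not deviate together (residual correlations -0.068, 0.060, -0.25 and 0.094, with 1 of 8 arrays correlating best with its own number), so the values show no pairing by number. Whether same-numbered cultures shared a plate or day is not known. Of 161 genes named by the rule 157 kept direction and call with the replicate block and 160 after either rescaling. IGFBP3 became called with the replicate block (adjusted p = 0.0473), with array weights and without untreated replicate 2, and its log2 difference ranged from -0.49 to -0.24 and its adjusted p from 0.000564 to 0.271 over all alternatives. Lists past camera numbered 20, 21 with the replicate block, 20 after either rescaling and 23 without dim genes, but 2 with an estimated correlation and 33 by fry. An estimated correlation widens the error of a list whose genes vary together, and fry compares a list with 0 rather than with other genes. For the cyclin-dependent kinase inhibitors and RB family, whose median was -0.14, fry gave the opposite direction to camera (upward, adjusted p = 2.38e-05), since members moved both ways. Sign changes of values that passed in neither setting are not counted. No background signal came with the values, so dim levels have no floor: without the 7009 genes that were above the array median on fewer than 4 arrays, 3217 were higher and 2605 lower among 11395, and the lists for unfolded protein response and ATF4 targets, macrophage and leukocyte markers and endothelial markers also passed. A dim gene that rose is kept by its treated arrays while an unchanged one is dropped, so the passes of the last 2 lists are largely built in: 3 of 8 leukocyte and 3 of 6 endothelial markers kept lay below the array median in untreated cells, and all of these rose.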

Other observations

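Families of genes sharing a symbol stem, and the members and parts named here, were chosen and tested only after the gene values were seen. Counts are of symbols, and a stem can hold pseudogenes, antisense RNAs and genes of other function. The test treats genes as independent, which members of a family may not be. NUP genes, mostly nucleoporins of the nuclear pore, fell in 15 of 23 cases and rose in 0 (median -0.30, one-sided Fisher's exact test, adjusted p = 3.35e-05), with NUP107 at -0.58 ± 0.090. The MCM genes, mostly of the replicative helicase, fell in 9 of 11 cases (adjusted p = 4.43e-04), which overlaps the DNA replication list. Genes of the splicing factor family SRSF fell in 8 and rose in 3 of 12 cases (median -0.28, adjusted p = 0.0102). CEP genes, mostly centrosomal, fell in 14 and rose in 8 of 37 cases (median -0.17, adjusted p = 0.0365), and KIF genes, mostly kinesins, fell in 15 and rose in 9 of 39 (median -0.075, adjusted p = 0.0271). Most of the KIF genes that fell, KIF15 and KIF11 among them, are also members of the mitosis and G2/M list. HSD genes, mostly hydroxysteroid dehydrogenases, fell in 9 and rose in 2 of 18 cases (median -0.16, adjusted p = 0.0365). The falls include the pseudogene HSD17B7P2, and the rises were HSD17B3, which makes testosterone (2.61 ± 0.091), and the pseudogene HSD3BP4. Small nucleolar RNAs (SNORD), many but not all of which guide RNA methylation, fell in 31 and rose in 5 of 115 cases (median -0.12, adjusted p = 0.0365). They are uncertain here because many are near-identical copies.

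Genes with the stem ATP rose in 31 and fell in 10 of 80 cases (median 0.045, adjusted p = 0.00744). Most of that came from the vacuolar proton pump, which acidifies lysosomes: of 24 ATP6V and ATP6AP symbols, mostly its subunits, 17 rose and 1 fell (median 0.29), led by ATP6V1D at 1.17 ± 0.12. VPS genes, named for vacuolar protein sorting in yeast but including the chromatin remodelling subunit VPS72 among the rises, rose in 15 and fell in 4 of 34 cases (median 0.19, adjusted p = 0.0473). PCDHB genes, of the beta protocadherin cluster, rose in 11 of 18 cases and fell in 0 (median 0.45, adjusted p = 0.0130), uncertain because they are near-identical copies. Of 310 families of at least 8 genes, tested in both directions for 620 tests in all, 10 passed, and the sign of each of their medians held after quantile normalization and after median centring. Among histones outside the replication-dependent list, H2BC12 (1.61 ± 0.075) and H2BC21 (1.12 ± 0.079) rose, again with the limit of near-identical copies. They were picked for their values, and the calls of the other histones outside the list were not counted.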
